A study of Mus musculus with 6 samples.

How the data were processed

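Transcript levels were measured in total RNA of mouse muscle, labelled as gastrocnemius, on 6 Agilent whole-genome arrays labelled with the dye Cy3. The arrays fell into 3 groups of 2: C57BL/10 mice on tap water (B10_tap), MDX mice on tap water (MDX_tap) and MDX mice on the bioceramic water JJ101 (MDX_JJ101), each for 10 months. Groups were taken from the labels, which number the replicates without saying whether they came from separate mice, so the replicates may be technical.

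The deposited intensity values were made by the authors with Agilent Feature Extraction 11.5.1.1, per the labels. In the deposited files the processed signal is a background-subtracted, spatially detrended intensity in which dim spots carry a surrogate value. The other deposited columns used here were 0 or 1 flags that mark spots as saturated, as outliers or as well above background. The authors' series table held values on the log2 scale. When tested against the array files, each of its columns had the same rank order as the median spot signal without background subtraction (Spearman correlation of 1 on each array). Its sorted columns differed by at most 0.0574, as quantile normalization leaves them, and it was used as an alternative only.

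The main values were the log2 of the processed signal minus the array's 75th percentile over the 59305 non-control spots. Spots flagged as outliers were left out, and the spots of a probe were averaged. Of 55681 probes, 27656 were paired with a gene symbol through the RefSeq accessions of a gene table of assembly GRCm38.p6, which covered 20972 symbols; the other 28025 kept the identifier of the array file. The array files give coordinates on the mm9 build, so the gene table served for names alone. A probe was kept if it was well above background on both arrays of at least 1 group, which left 27258 probes. For each gene the probe with the highest mean was used, giving 20869 genes and transcripts, 13952 with a symbol and 6917 without, and 8 missing values. Differences are given on the log2 scale. Where no array of one group was well above background, the fold is given as a bound ("at least"), computed against the mean over that group's arrays of the lowest signal called well above background; no fold is given where the other group did not exceed that level. Signal over background, in place of a read count, sets how far down a change could be measured, and the number of arrays limits the precision.

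The 3 groups were fitted together with limma 3.58.1 in R 4.3.3, with 1 coefficient per group and 3 residual degrees of freedom, to which the moderated test added 2.21 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01 and adjusted over 31 lists fixed before the data were examined. They covered the dystrophin complex, muscle regeneration, fibrosis, macrophages, T and NK cells, B and plasma cells, neutrophils, mast cells, cytokines, interferon, antioxidants, NADPH oxidase, oxidative phosphorylation, fatty acid oxidation and glycolysis. The others were slow fibre, fast fibre, calcium handling, atrophy, heat shock, muscle stress, adipocyte, endothelial, smooth muscle, Schwann and nerve, erythroid, cell cycle, circadian clock, immediate early, ribosomal protein and sex check lists. The groups, comparisons, tests, lists, the rule for named genes and all alternatives but those stated were chosen before the data were examined. By that rule the text names, for each comparison, Dmd and Utrn. It names the 8 highest and 8 lowest genes past the threshold whose arrays did not overlap, leaving out names that are only identifiers and repeats within a family. It also names up to 4 members with the smallest p of each list past the threshold, all members of a list of at most 5 genes, and, where fewer than 5 genes passed in a direction, the 5 with the smallest p. Some genes that the rule names are not reported here. A further 9 lists were written after the values were seen: heart regulators and hormones, heart contractile, limb muscle regulators, skeletal muscle of any fibre type, amino acid response, glucocorticoid-induced, liver, clock activators and clock output.

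Correlations between 2 sets of differences that share arrays were set against 100 simulated data sets without effects. The same steps were tested on simulated data over 20861 genes, with independent noise at each gene's moderated variance. With 200 changed genes, the share recovered at a log2 change of 1 was 51.0% for MDX_tap against B10_tap, 53.0% for MDX_JJ101 against MDX_tap and 58.0% for MDX_JJ101 against B10_tap. At a log2 change of 2 these shares were 92.0%, 96.0% and 95.0%, and false calls made up 7.14%, 4.49% and 8.38% of the calls. With 4000 changed genes, the shares recovered at a log2 change of 1 were 90.2%, 91.4% and 89.7%, and false calls made up 4.02%, 4.14% and 3.77%. In each comparison, 1 simulated shifted list was found by camera at both correlation settings and 0 other lists were called. The simulated genes were not correlated, whereas the correlations estimated within lists in the data ran from -0.066 to 0.90. The simulation therefore does not tell how either setting does on correlated genes. Nor did any simulated array deviate in many genes at once, so the shares of recovered genes and false calls may not hold for the data.

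Alternatives changed 1 choice at a time, except that normexp came together with quantile normalization and the median signal, and that the authors' table differed in signal, background subtraction and normalization at once. They were normexp background correction with offset 50 and quantile normalization, quantile normalization alone, median centring, the authors' log2 table, no filter or a filter on all arrays, a floor for dim values, every probe or the mean over probes, a replicate block, trend and robust variances, array weights, a fit of 2 groups, a minimum change of 2-fold, the slide column as a block and each array left out in turn. For lists they also were an estimated correlation and limma's fry. Normexp was run on the median signal, because the files hold no mean signal. Scaling on 7 spike-in probes, list tests with every probe, and runs of the lists chosen later under 5 other scalings and without each array were added after the data were seen. With spike-in scaling limma's smallest adjusted p was 7.54e-38 for MDX_tap against B10_tap, 2.97e-87 for MDX_JJ101 against MDX_tap and 4.42e-93 for MDX_JJ101 against B10_tap. In the main fit these were 0.0119, 0.00752 and 0.00346. Adjusted p and counts of genes under spike-in scaling are therefore not on a footing with those of the other fits. Spot images and probe sequences were not analysed here.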

Results

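Transcript levels were compared in muscle RNA, labelled as gastrocnemius, from wild-type C57BL/10 mice and from MDX mice, which lack functional dystrophin. Of 3 groups with 2 arrays each, B10_tap held wild-type mice on tap water, MDX_tap held MDX mice on tap water and MDX_JJ101 held MDX mice on JJ101, which the labels call a bioceramic water. The mice had been on their water for 10 months. Of 59305 spots per array, the share well above background was 51.6% and 51.4% in B10_tap, 49.6% and 48.1% in MDX_tap, and 43.8% and 42.5% in MDX_JJ101. The correlation between the replicates of a group was 0.995 in B10_tap, 0.993 in MDX_tap and 0.989 in MDX_JJ101, and the SD of their difference was 0.29, 0.37 and 0.48 on the log2 scale. All 6 arrays lay on 1 slide. The MDX_JJ101 arrays lay in one row of it (columns 3 and 4) and all other arrays in the other row (B10_tap in columns 1 and 2, MDX_tap in columns 3 and 4). Slide row and JJ101 therefore cannot be told apart. MDX_tap and B10_tap shared a row but not their columns, so slide column and genotype cannot be told apart either. MDX_JJ101 and B10_tap differed in both row and column. Levels below are log2 signals relative to the array's 75th percentile, and differences are given as log2 values or as folds.

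Transcripts typical of heart were present on all arrays. Myh6, the alpha myosin heavy chain of heart muscle, had a mean level of 10.42 in B10_tap, 10.24 in MDX_tap and 10.30 in MDX_JJ101 (n = 2 each), and Nppa, which encodes atrial natriuretic peptide, had 7.29, 8.75 and 9.66. All 12 genes of a list of heart regulators and hormones, among them Gata4, Nkx2-5 and Tbx5, and all 8 heart contractile genes were well above background on the 6 arrays. Of 20 limb muscle regulators, 4 were well above background on all arrays, 12 on no array and 4 on some. These lists were chosen after the values were seen, and they bear on every muscle gene group described here. In MDX_JJ101 against MDX_tap, 5 of the 12 heart regulators and hormones rose (median 0.56) and 0 fell.

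**Figure D1:**
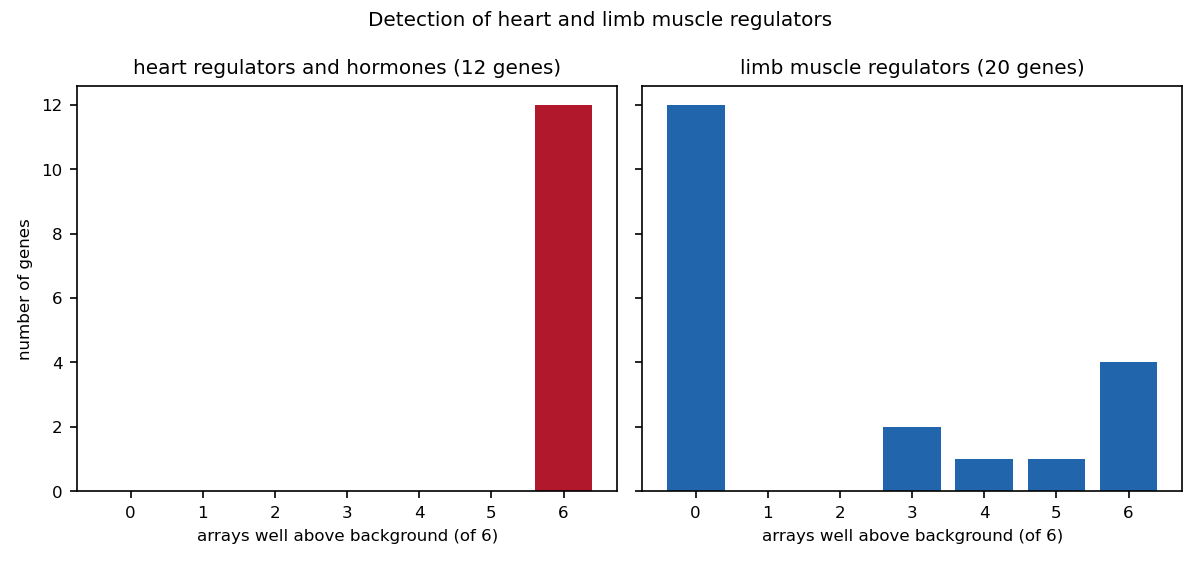
Number of genes (bars) by the number of arrays, of 6 in 3 groups, on which the gene's probe was well above background, for 12 heart regulators and hormones and for 20 limb muscle regulators. All 12 heart genes reached 6 arrays, and 12 of the 20 limb genes reached 0.

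The first comparison asked how dystrophic muscle differed from wild-type muscle when both groups drank tap water. By camera at its preset correlation, transcripts of fibrosis, macrophages and mast cells were higher in MDX_tap as groups and circadian clock transcripts lower, but none of these calls held with an estimated correlation (adjusted p = 0.682 for each). No single member of these lists passed over all genes. Dmd, the dystrophin gene, had a level of 1.06 ± 0.00034 (SD, n = 2) in B10_tap and -0.55 ± 0.41 in MDX_tap, a difference of -1.61 (SE 0.21, 3.06-fold lower), which did not pass over all genes (adjusted p = 0.0717) and had an adjusted p of 0.00788 over the list alone. Dmd passed under 8 alternatives, with adjusted p between 0.00401 with spike-in scaling and 0.0425 with median centring, and the range over all its alternatives reached 0.261 without B10_tap replicate 2. Utrn, which encodes the dystrophin relative utrophin, differed by 0.09 (SE 0.16, adjusted p = 0.766), and by -0.10 without MDX_tap replicate 2 and 0.27 without MDX_tap replicate 1.

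By limma's test 5 of 20869 genes and transcripts passed between MDX_tap and B10_tap, all 5 lower in MDX_tap, and 4383 had an unadjusted p under 0.05. All 5 were well above background on both B10_tap arrays and on none of the MDX_tap or MDX_JJ101 arrays. They were chosen here after their values were seen, since 4 have no gene symbol. 1700028P14Rik was at least 3.96-fold lower (adjusted p = 0.0119) and a RefSeq non-coding transcript was at least 2.59-fold lower (adjusted p = 0.0119). The other 3 were transcribed regions at chromosome 11 from 50994911 to 51050704, chromosome 12 from 33606225 to 33638225 and chromosome 13 from 19611679 to 19620954 of the mm9 build, which were at least 3.52-fold, 5.94-fold and 1.34-fold lower. The count ran from 0 without a filter (limma, 5113 at an unadjusted p under 0.05) through 15 with every probe, 125 with 2 groups fitted and 151 to 407 with 7 other choices to 413 with spike-in scaling. It also moved with every array and was 190 without B10_tap replicate 1, 98 without B10_tap replicate 2, 111 without MDX_tap replicate 1, 81 without MDX_tap replicate 2, 62 without MDX_JJ101 replicate 1 and 17 without MDX_JJ101 replicate 2.

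Genes with the smallest p that did not pass in MDX_tap against B10_tap were Cyp1b1 at 1.64 (SE 0.14), which encodes a cytochrome P450, Cytip at 1.70 (SE 0.14), which encodes a protein of activated lymphocytes, and the transcription factor genes Maff at 1.30 (SE 0.11) and Fosl2 at 1.60 (SE 0.14). Together with the kinase gene Stk17b at 1.07 (SE 0.10) and Cyp4f14 at -1.60 (SE 0.15) they had an adjusted p of 0.0528. Other low values were those of Dbp at -1.36 (SE 0.14, adjusted p = 0.0595), Mettl11b at -1.23 (SE 0.14, 0.0679) and the DNA polymerase gene Poln at -0.86 (SE 0.10, 0.0679). In each of these genes the MDX_tap arrays lay apart from the B10_tap arrays. The genes were picked for their small p, so this is no separate evidence.

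By camera, 13 of the 31 lists passed in MDX_tap against B10_tap, 11 upwards and 2 downwards, and 0 passed with an estimated correlation (lowest adjusted p = 0.682). There 0 lists had an unadjusted p under 0.05, the lowest being 0.0511, and fry passed 1 list, heat shock and ER stress (adjusted p = 0.0128). Fibrosis and extracellular matrix genes had a median of 1.03, with 26 of 27 members positive (adjusted p = 5.1e-15, and adjusted p = 0.682 with an estimated correlation). No member passed over all genes, and 21 passed upwards when adjusted over the list alone. Examples are Ccn2, a connective tissue growth factor, at 1.63 (SE 0.15, adjusted p = 0.0528), the collagen-crosslinking enzyme gene Lox at 1.47 (SE 0.21, 0.0788), Timp1, an inhibitor of matrix proteases, at 2.99 (SE 0.54, 0.102) and fibronectin (Fn1) at 1.54 (SE 0.28, 0.103). Lox was 2.51 without B10_tap replicate 1 and 2.28 without MDX_JJ101 replicate 2. Macrophage genes had a median of 0.99, with 21 of 22 members positive and 16 past over the list alone (adjusted p = 6.7e-12, and 0.682 as adjusted p with an estimated correlation). Spp1, which encodes osteopontin, was at least 17.1-fold higher (adjusted p = 0.0595) and was well above background on neither B10_tap array. The lipid receptor gene Trem2 stood at 1.71 (SE 0.24, 0.0813), Gpnmb at 2.40 (SE 0.37, 0.088) and the galectin gene Lgals3 at 2.36 (SE 0.40, 0.0976). Mast cell genes had a median of 1.45, or 1.00 with unmeasured members at their bounds, with 6 of 7 positive and 5 past over the list alone (adjusted p = 0.000185, and adjusted p = 0.682 with an estimated correlation). Of these, the protease gene Mcpt4 stood at 1.99 (SE 0.21, 0.0595), Hdc, the histamine-forming enzyme, at 1.00 (SE 0.21, 0.116), and Fcer1a and Cma1 were at least 1.51-fold and 2.52-fold higher (0.0528 and 0.167). The mast cell median was 0.37 with normexp and quantile normalization and 0.56 with the authors' table.

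Cytokine and NF-kB genes had a median of 0.53 in MDX_tap against B10_tap, with 20 of 22 positive and 5 past over the list alone (adjusted p = 3.8e-07, and adjusted p = 0.691 with an estimated correlation). The chemokine genes Ccl6 at 1.27 (SE 0.13, adjusted p = 0.0614), Ccl9 at 1.30 (SE 0.14, 0.0652) and Ccl8 at 2.46 (SE 0.42, 0.0987) and the NF-kB inhibitor gene Nfkbia at 0.52 (SE 0.10, 0.112) had its smallest p. The median was 0.32 without MDX_tap replicate 1 and 1.14 without MDX_tap replicate 2. Cell cycle genes had a median of 0.49, with 15 of 16 positive and 0 past over the list alone (adjusted p = 2.1e-05, and adjusted p = 0.697 with an estimated correlation); Mki67 stood at 0.76, Mcm3 at 0.53, Mcm6 at 0.55 and Bub1b at 1.08, and the median was 0.27 with normexp and quantile normalization. NADPH oxidase genes had a median of 0.84 with 4 of 7 past over the list alone (adjusted p = 0.00131, and adjusted p = 0.691 with an estimated correlation); Ncf1 stood at 0.97, Nox4 at 1.71, Rac2 at 0.89 and Ncf4 at 0.84, and the call ended without MDX_tap replicate 1 (median 0.54, 0.0547), where Rac2 was 0.53. Immediate early genes, which respond to handling of tissue, had a median of 0.60 with 13 of 15 positive and 2 past over the list alone (adjusted p = 0.000587, and 0.697 as adjusted p with an estimated correlation). Egr2 stood at 2.17, Nr4a1 at 1.63, Atf3 at 1.17 and Maff at 1.30. The list's median was 0.14 (adjusted p = 0.429) without MDX_tap replicate 1, where Atf3 was 0.66, 1.17 without MDX_tap replicate 2, 0.37 with normexp and quantile normalization and 0.39 with the authors' table. Interferon response genes had a median of 0.27 (adjusted p = 0.0166, and adjusted p = 0.974 with an estimated correlation), with Ifit2 at 0.50, Oas1a at 0.82, Ifi44 at 0.67 and Ifit1 at 0.52; 0 members passed over the list alone. Oas1a, Ifi44 and Ifit1 were 0.38, 0.42 and 0.22 without MDX_tap replicate 1, and Oas1a and Ifit1 were 1.26 and 0.81 without MDX_tap replicate 2. That median was -0.04 (adjusted p = 0.806) without MDX_tap replicate 1 and 0.56 without MDX_tap replicate 2, and the call also ended without B10_tap replicate 2 (0.170), with median centring (0.0536) and without a filter (0.108).

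Muscle stress genes had a median of 0.47 in MDX_tap against B10_tap with 6 of 12 past over the list alone (adjusted p = 0.00292, and adjusted p = 0.682 with an estimated correlation). The examples were Nmrk2 at 1.44, Runx1 at 1.09, Gadd45b at 0.58 and Ankrd1, a strain-responsive gene of muscle and heart, at 0.65. Heat shock and ER stress genes had a median of 0.18 with 2 of 15 past over the list alone (adjusted p = 0.0081, and adjusted p = 0.682 with an estimated correlation); the chaperone genes Hsp90aa1, Hsph1, Dnajb1 and Hspa1a stood at 0.75, 0.78, 0.79 and 1.23. Without MDX_tap replicate 1 Dnajb1 was 0.51 and Hspa1a 0.57, and without MDX_tap replicate 2 Hspa1a was 1.89 and the median 0.094. The call ended without a filter (0.0598). Ribosomal protein genes had a median of 0.11 with 20 of 22 positive (adjusted p = 0.00304, and adjusted p = 0.697 with an estimated correlation), with Rpl3 at 0.27, Rps4x at 0.20 and Rps6 at 0.15; the call ended with spike-in scaling (0.263). Oxidative phosphorylation genes had a median of -0.20 with 28 of 29 negative (adjusted p = 0.00118, and adjusted p = 0.807 with an estimated correlation). Uqcrc1 stood at -0.40, Cox5b at -0.28 and Sdhc at -0.27, 0 members passed over the list alone, and the call ended without MDX_tap replicate 1 (median -0.12, 0.0598) and with spike-in scaling (0.263). Median centring put the heat shock, ribosomal and oxidative phosphorylation medians at 0.35, 0.29 and -0.028, with each call kept. Circadian clock genes had a median of -0.72 with 9 of 13 lower and 2 higher when adjusted over the list alone (adjusted p = 0.00301, and adjusted p = 0.682 with an estimated correlation). The lower members included Dbp at -1.36, Ciart at -1.64, Bhlhe41 at -0.63 and Hlf at -1.0, all also members of the clock output list written later. The median was -0.42 with normexp and quantile normalization and -0.47 with the authors' table.

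The other 18 lists did not pass in MDX_tap against B10_tap. Their medians were -0.03 for the dystrophin complex, -0.16 for muscle regeneration, 0.51 for T and NK cells, -0.24 for B and plasma cells, 0.10 for neutrophils, -0.02 for antioxidants, -0.16 for fatty acid oxidation, -0.08 for glycolysis and glycogen, -0.13 for slow fibres and -0.21 for fast fibres. Over the list alone, single members passed for the dystrophin complex (1 lower), regeneration (1 higher, 1 lower), B and plasma cells (1 lower), endothelium (2 higher, 1 lower) and nerve (1 higher, 2 lower). Calcium handling had -0.04, atrophy and autophagy -0.08, adipocytes 0.10, endothelium -0.14, smooth muscle and pericytes 0.02, Schwann cells and nerve -0.17, red blood cells -0.18 and the sex check 0.04. The antioxidant median was negative whereas its mean of 0.07 and its test pointed upwards. Of the sex check genes, the Y-linked Ddx3y, Eif2s3y and Uty stood at 0.11, 0.02 and 0.04, and Xist and Kdm5d were not among the genes tested.

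The second comparison asked how MDX mice on JJ101 differed from MDX mice on tap water. By camera at its preset correlation, transcripts of glycolysis, fatty acid oxidation and autophagy were higher as groups in MDX_JJ101 than in MDX_tap and transcripts of macrophages and matrix lower, but none of these calls held with an estimated correlation (adjusted p = 0.571 for each). By limma's test 7529 of 20869 genes and transcripts passed (36.1%), 4160 higher and 3369 lower. Of them 5327 had a symbol (3428 higher and 1899 lower), and 1718 had changed at least 2-fold (428 higher and 1290 lower). The count moved with the arrays fitted, and it was 4816 with only the 2 groups compared. Without B10_tap replicate 2 it was 0 by limma, with a smallest adjusted p of 0.0508 and 8855 genes at an unadjusted p under 0.05, so that no call named for this comparison held there. It was 2131 without B10_tap replicate 1, 1873 without MDX_tap replicate 1, 301 without MDX_tap replicate 2 and 4345 without MDX_JJ101 replicate 2. Of 72 named genes that passed, 35, 22, 6 and 49 still did in these cases and 68 without MDX_JJ101 replicate 1, and none turned its direction. With the slide column as a block it was 0, with 8857 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0578. It was 6517 with a replicate block, which groups the MDX arrays in the same way. Either block lowers the residual degrees of freedom. Direction depended on scaling: 79 of 3712 genes were higher with spike-in scaling, which was chosen after the data were seen and shifted the median of all genes by -0.43, and 5692 of 7590 with median centring, which shifted it by 0.23. For 903 of the 7529 genes called in the main fit, 1 group was well above background on no array, so no size beyond a bound was measured. Among 1704 called genes with several probes, 215 had a probe of opposite direction.

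The genes that rose most in MDX_JJ101 against MDX_tap were Zbtb16, a transcription factor gene induced by glucocorticoids, at 2.56 (SE 0.39, 5.92-fold, adjusted p = 0.0139), the arrestin relative Arrdc2 at 2.39 (SE 0.25, 0.0128) and Chac1, which encodes a glutathione-degrading enzyme, at 2.07 (SE 0.26, 0.0128). They were followed by the glutamate receptor gene Grin2c at 1.90, the hypoxia-inducible factor gene Hif3a at 1.86, Nrap, an anchoring protein of sarcomeres and intercalated discs, at 1.74, Cnksr1 at 1.74 and the potassium channel gene Kcnj4 at 1.64. Among genes with a measured level in both groups, the lowest included the small non-coding RNAs Rnu3b1 at -4.28 (SE 0.66, 19.4-fold, 0.0139), Rnu1b6 at -4.05 (SE 0.41, 16.6-fold, 0.0128), Rnu2-10 at -3.74 and Rmrp, the RNA of RNase MRP, at -3.15, while Myh4, given below as a bound, was lower still. Also lowest were the fast troponin C gene Tnnc2 at -4.06 (SE 0.82, 16.7-fold, 0.0208), the calcium buffer gene Pvalb at -2.55 (SE 0.65), Cfd, which encodes the adipocyte protein adipsin, at -3.11 (SE 0.71) and the dendritic cell marker Cd83 at -2.27 (SE 0.17). Both MDX_JJ101 arrays lay beyond both MDX_tap arrays on the genes named as highest and lowest, as the naming rule required. Pvalb was -1.54 without MDX_tap replicate 2, Cfd was -1.99 without MDX_JJ101 replicate 2, and Tnnc2 was -2.78 without MDX_tap replicate 2 and -5.35 without MDX_tap replicate 1.

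**Figure D2:**
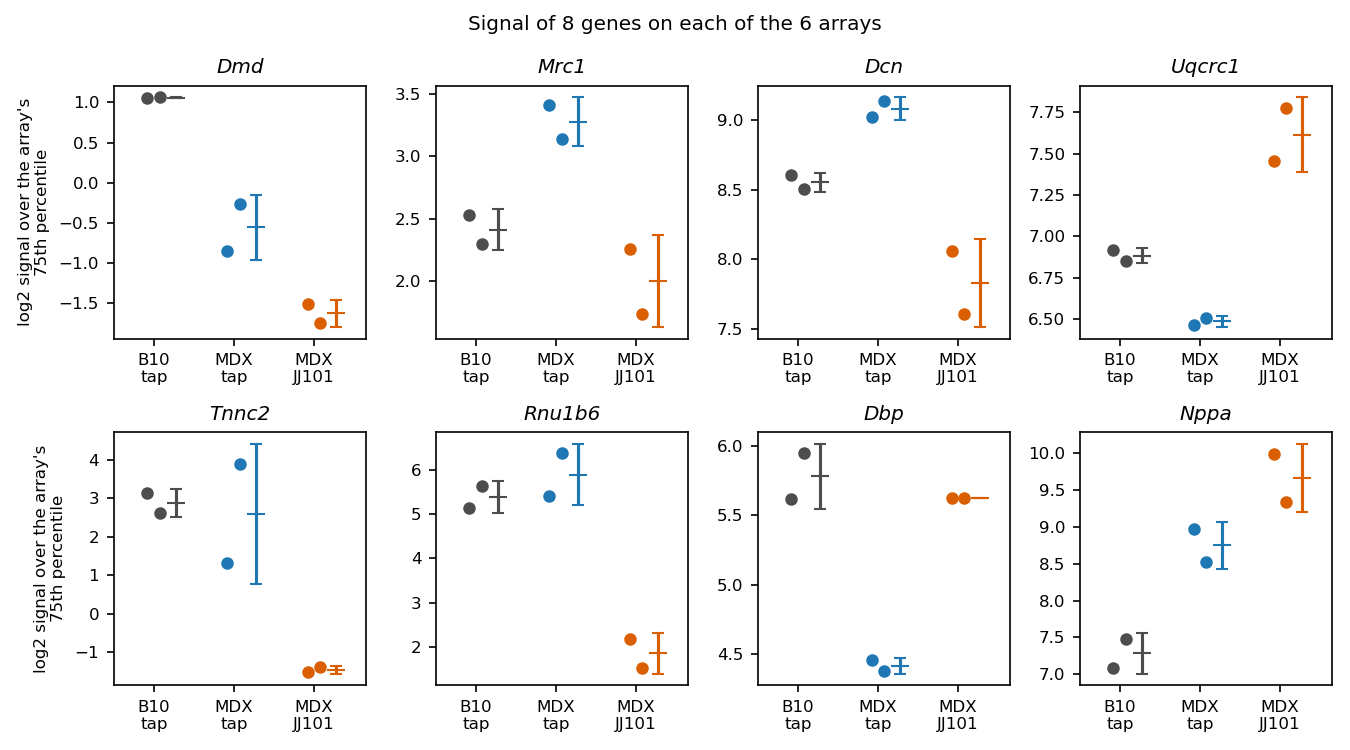
Level of 8 genes on each array, as log2 signal relative to the array's 75th percentile, with points for arrays and a dash and bar for the mean ± SD of each group (n = 2). Dmd had means of 1.06 in B10_tap, -0.55 in MDX_tap and -1.62 in MDX_JJ101, and Tnnc2 had 2.88, 2.60 and -1.46; both kept their direction in the MDX_JJ101 comparisons under each scaling tried.

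Dmd fell by 1.07 in MDX_JJ101 against MDX_tap (SE 0.21, adjusted p = 0.0205; 0.00901 over the list alone), and Utrn stood at -0.43 (SE 0.16, adjusted p = 0.0854; 0.0496 over the list alone) and at -0.24 without MDX_tap replicate 2. The Dmd call ended without B10_tap replicate 1 (0.0575), B10_tap replicate 2 (0.0593), MDX_tap replicate 2 (0.0572) and MDX_JJ101 replicate 2 (0.0754) and with the column block (0.0709), and its value was -0.65 with normexp and quantile normalization. Of 15 dystrophin complex genes, 6 rose and 3 fell (7 and 5 over the list alone; camera adjusted p = 0.433). Those that rose included Dag1 at 0.92, which encodes dystroglycan, the sarcoglycan gene Sgca at 0.85 and Sspn at 0.62. Beside Dmd, the laminin gene Lama2 fell by 0.47 and Sntb2 by 0.82.

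By camera, 14 lists passed in MDX_JJ101 against MDX_tap, 6 upwards and 8 downwards, and 0 with an estimated correlation, where each of the 14 had adjusted p = 0.571 with an estimated correlation. The lowest unadjusted p there was 0.166, so that 0 lists lay under 0.05, and fry passed 1 list, heat shock and ER stress (adjusted p = 0.00932). Without MDX_tap replicate 1 camera passed 8 lists. Oxidative phosphorylation genes rose in 17 of 29 members (18 over the list alone; median 0.40, adjusted p = 4.8e-06), whereas their median was -0.03 under spike-in scaling. Uqcrc1 rose by 1.13 (SE 0.14, 2.19-fold, 0.0128), Cyc1 by 0.75 (SE 0.10), Sdhc by 0.68 (SE 0.10) and Ndufv1 by 0.66 (SE 0.10), which encode subunits of the respiratory chain. Glycolysis and glycogen genes rose in 10 of 18 members (12 over the list alone), with a median of 0.56 and all 18 positive (adjusted p = 6.5e-05), among them Pgam2 at 0.84, Tpi1 at 0.80, the glycogen synthase gene Gys1 at 1.11 and the glucose transporter gene Slc2a4 at 0.79. Fatty acid oxidation genes rose in 10 of 22 members (11 over the list alone; median 0.49, adjusted p = 0.000565). Ppard rose by 0.90, Ppara by 0.77, Mlycd by 0.97 and Acads by 1.24. Atrophy and autophagy genes rose in 7 of 17 members (10 over the list alone; median 0.61, adjusted p = 0.000985), with the autophagosome genes Map1lc3b at 1.03 and Map1lc3a at 0.84, Klf15 at 1.03 and Eif4ebp1 at 0.75. Antioxidant genes rose in 10 of 25 members and fell in 1 (both counts the same over the list alone; median 0.34, adjusted p = 0.0273), whereas their median was -0.09 under spike-in scaling. Sod2 rose by 0.63, Mt1 by 1.11, Gss by 0.59 and Gsta4 by 0.79, and the gene that fell was Nfe2l2 at -0.54, which encodes the NRF2 factor. The antioxidant call ended under 6 alternatives to the scaling or filter (adjusted p from 0.0571 to 0.263), with a median of 0.17 under normexp with quantile normalization, quantile normalization alone and the authors' table, and without MDX_JJ101 replicate 2 (0.0933). Circadian clock genes rose in 7 of 13 members (7 higher and 1 lower over the list alone; median 0.57, adjusted p = 0.0273). Dbp rose by 1.21 (SE 0.14), Nr1d1 by 1.11 (SE 0.13), Ciart by 1.57 (SE 0.23) and Cry2 by 0.80 (SE 0.13), and the call ended without MDX_tap replicate 1 (0.0756), MDX_JJ101 replicate 2 (0.111) or a filter (0.292). Under spike-in scaling the medians of the glycolysis, fatty acid oxidation, atrophy and circadian clock lists were 0.13, 0.056, 0.18 and 0.14, with each call kept. Median centring put the oxidative phosphorylation and antioxidant medians at 0.63 and 0.56. For oxidative phosphorylation 3 other scalings gave 0.22 to 0.26, and normexp with quantile normalization put the clock median at 0.34. The authors' table put the fatty acid median at 0.31, and without MDX_JJ101 replicate 2 the atrophy median was 0.38.

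Macrophage genes fell in 15 of 22 members and rose in 1, Itgam (17 and 1 over the list alone), in MDX_JJ101 against MDX_tap, with a median of -1.18 (adjusted p = 7.2e-05, and adjusted p = 0.571 with an estimated correlation as for each list here). Mrc1, the mannose receptor gene, fell by 1.27 (SE 0.22, 2.42-fold, 0.0155), the lysozyme genes Lyz1 and Lyz2 by 1.5 and 1.34, and Cd14 by 1.04. Fibrosis and extracellular matrix genes fell in 6 of 27 members (6 over the list alone; median -0.73, adjusted p = 0.000925). The proteoglycan genes Dcn at -1.25 (SE 0.17, 0.013) and Lum at -1.62 (SE 0.29), the protease gene Mmp3 at -1.27 and the collagen gene Col5a2 at -1.23 had its smallest p, and Col5a2 was -0.79 without MDX_JJ101 replicate 2. Interferon response genes fell in 4 of 17 members (4 over the list alone; median -0.72, adjusted p = 0.00159), which were Ifit2 at -0.72, Gbp3 at -1.34, Ifit1 at -1.41 and Gbp2 at -0.90. Cytokine and NF-kB genes fell in 7 of 22 members and rose in 1, Nfkb2 (7 and 1 over the list alone; median -0.97, or -0.92 with bounds, adjusted p = 0.00642), with Ccl9 at -0.89, Ccl6 at -0.77, the adhesion gene Vcam1 at -1.04 and Ptgs2 at least 1.93-fold lower. T and NK cell genes fell in 4 of 13 members (4 over the list alone; median -0.72, adjusted p = 0.0315). Prf1, which encodes perforin, fell by 0.91, Cd3d by 1.52 and Cd3g by 2.30, and Cd3g was -1.42 without MDX_JJ101 replicate 2. Without MDX_tap replicate 1 the calls of the T and NK cell (median -0.26, 0.162), cytokine (-0.59, 0.103) and interferon (-0.39, 0.0706) lists ended, and the first also ended with the filter on all arrays (-0.20, 0.0683). The T and NK cell median was -1.12 without MDX_tap replicate 2, -1.20 without MDX_JJ101 replicate 1, -0.37 with normexp and quantile normalization and -0.43 with the authors' table. The cytokine median was -0.61 with normexp and quantile normalization and -0.57 with the filter on all arrays, and the fibrosis median was -0.39 without MDX_JJ101 replicate 2. Under spike-in scaling the fibrosis, interferon and T and NK cell medians were -1.16, -1.15 and -1.15.

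Endothelial genes fell in 6 of 11 members (6 over the list alone) in MDX_JJ101 against MDX_tap, with a median of -0.46 (adjusted p = 0.0293, and adjusted p = 0.571 with an estimated correlation as for each list here). The tight junction gene Cldn5 fell by 1.21 (SE 0.16), Tek by 0.75, Emcn by 0.57 and Vwf, the von Willebrand factor gene, by 0.73. That call ended without MDX_tap replicate 1 (0.159), without MDX_JJ101 replicate 1 (0.0502) and with spike-in scaling (0.142). Cell cycle genes fell in 3 of 16 members (0 over the list alone; median -0.49, or -0.43 with bounds, adjusted p = 0.0273), which were Mki67 at -0.82, Mcm3 at -0.51 and Cdk1, at least 1.42-fold lower, and Top2a did not pass at an adjusted p of 0.0528. The call ended without MDX_tap replicate 1 (0.119) and MDX_JJ101 replicate 2 (median -0.32, 0.0944), where Mcm3 was -0.33. The median was -0.24 with normexp and quantile normalization and -0.29 with the authors' table. Ribosomal protein genes fell in 7 of 22 members (6 over the list alone; median -0.20, adjusted p = 0.0315), whereas their median was 0.03 with median centring (0.235). Rpl30 stood at -0.52, Rpl5 at -0.50, Rps18 at -0.59 and Rps4x at -0.38. That call ended with the mean over probes (0.0675), spike-in scaling (0.427), the column block (0.0648) and without MDX_tap replicate 1 (0.103), MDX_tap replicate 2 (0.0508) or MDX_JJ101 replicate 2 (median -0.12, 0.0944), while 3 other scalings gave medians of -0.34 to -0.31. Under spike-in scaling the endothelial, cell cycle and ribosomal medians were -0.89, -0.92 and -0.63, and with median centring the first pair stood at -0.23 and -0.26.

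**Figure D3:**
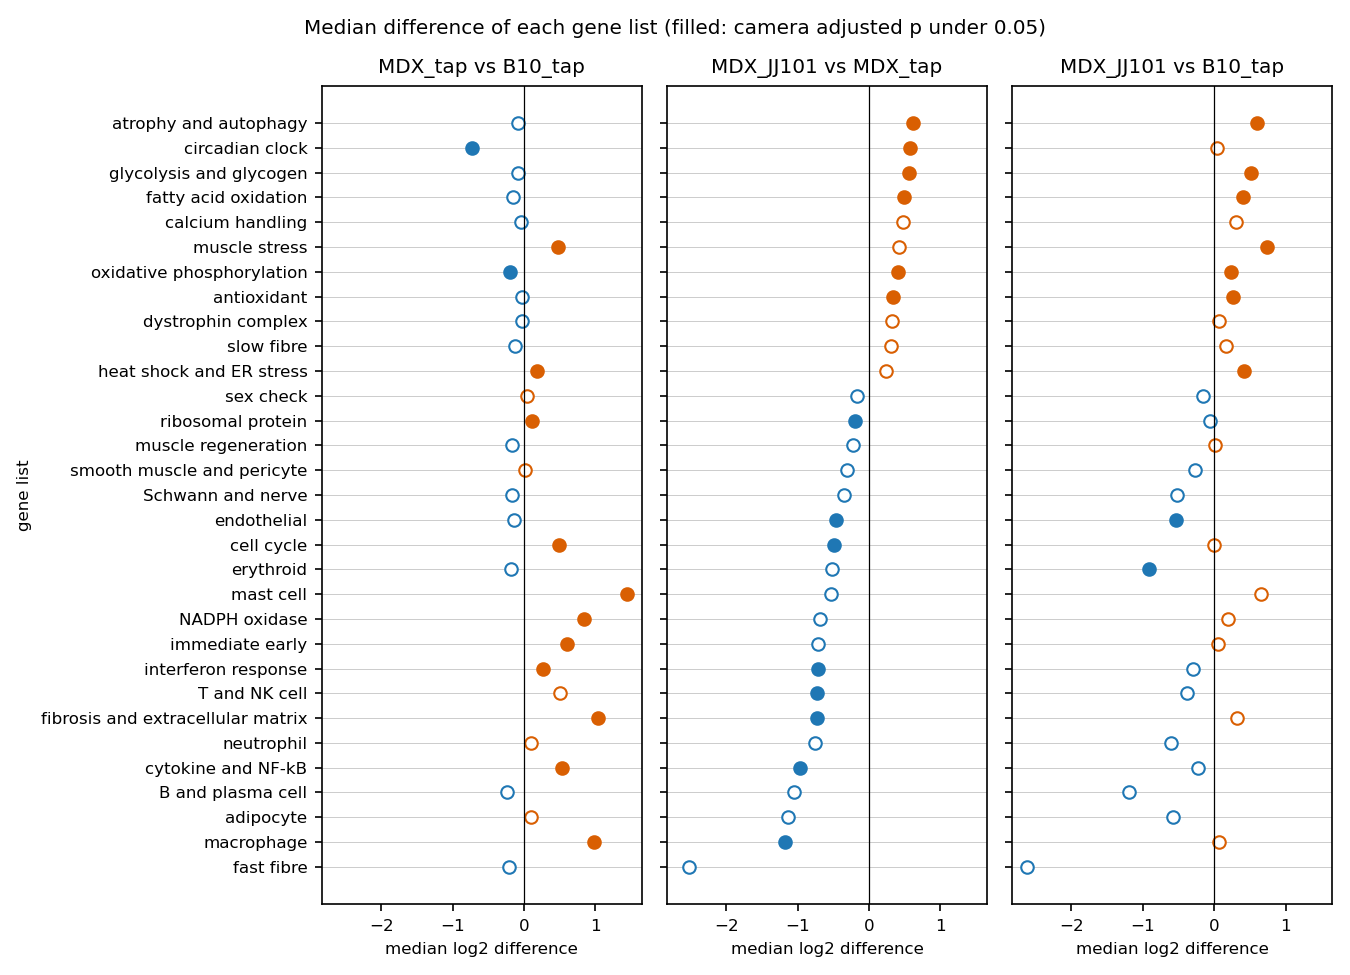
Median log2 difference of the measured members of 31 gene lists in each of the 3 comparisons, with filled points where camera's adjusted p was under 0.05, orange above 0 and blue below 0. The first and second comparisons share the MDX_tap arrays, which by itself favours medians of opposite sign. Macrophage genes had medians of 0.99, -1.18 and 0.07; under spike-in scaling the medians of oxidative phosphorylation and antioxidant genes turned negative in both MDX_JJ101 comparisons, those of fatty acid oxidation and heat shock genes did in MDX_JJ101 against B10_tap, and with median centring that of ribosomal protein genes turned positive in MDX_JJ101 against MDX_tap.

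Fast fibre genes split within their list in MDX_JJ101 against MDX_tap, where 6 of 12 members fell and 2 rose (7 and 2 over the list alone; camera adjusted p = 0.198). The median was -2.53, or -1.66 with unmeasured members at their bounds. The fast myosin gene Myh4 was at least 46.3-fold lower (adjusted p = 0.0128), Myh1 at least 3.67-fold and Actn3 at least 2.70-fold. None of these was well above background on either MDX_JJ101 array, while Tnnt3, well above background on 1 of those arrays, fell by 3.76. The calcium pump gene Atp2a1 rose by 1.34 (SE 0.17) and Mybpc2 by 0.84 (SE 0.12). The 6 genes that fell differed by a median of 2.60 between the MDX_tap arrays, replicate 2 being higher. Genes of the list of slow and oxidative fibres rose in 3 of 11 members and fell in 1, the fast oxidative (type 2A) myosin gene Myh2, at least 3.60-fold lower (3 and 1 over the list alone; camera adjusted p = 0.15); their median of 0.30 and the test pointed upwards and their mean of -0.03 downwards.

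Another 14 lists did not pass in MDX_JJ101 against MDX_tap. Calcium handling genes rose in 8 and fell in 2 of 19 (median 0.48, adjusted p = 0.0733), with the calcium channel gene Cacna1s at 1.18 and the entry channel gene Orai1 at 0.65. Adipocyte genes fell in 6 and rose in 3 of 11 (median -1.13, or -0.61 with bounds, 0.191), with Adipoq, the adiponectin gene, at least 2.06-fold lower. Heat shock and ER stress genes rose in 4 and fell in 3 of 15 (median 0.24, 0.154), muscle stress genes rose in 4 and fell in 1 of 12 (median 0.42, 0.154), and regeneration genes rose in 1 and fell in 3 of 11 (median -0.23, 0.416). Medians were -1.05 for B and plasma cells (3 of 6 fell), -0.75 for neutrophils (2 of 5), -0.53 for mast cells (1 of 7), -0.69 for NADPH oxidase (4 of 7), -0.52 for red blood cells (3 of 7) and -0.72 for immediate early genes (2 of 15). Smooth muscle and pericyte genes had -0.30 (3 of 10 fell, 1 rose), Schwann and nerve genes -0.35 (2 of 9 fell) and the sex check -0.17, where Ddx3y fell by 0.52 (adjusted p = 0.0321) and Eif2s3y and Uty stood at -0.17 and 0.09. Over the list alone the counts differed for calcium handling (9 rose, 3 fell), adipocytes (4 and 7), heat shock (6 and 3), neutrophils (3 fell), smooth muscle (5 fell), Schwann and nerve (1 fell) and immediate early genes (1 fell).

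The third comparison asked how MDX mice on JJ101 differed from wild-type mice on tap water. By camera at its preset correlation, muscle stress and glycolysis genes were higher as groups in MDX_JJ101, calls that did not hold with an estimated correlation (adjusted p = 0.885 for each). Among single genes Mthfd2 and Chac1 rose, and Dmd, Tnnc2 and Rnu3b1 fell. By limma's test 7008 of 20869 genes and transcripts passed (33.6%), 3376 higher and 3632 lower. Of them 4436 had a symbol (2873 higher and 1563 lower), and 1971 had changed at least 2-fold. The count was 605 without B10_tap replicate 1, 427 without B10_tap replicate 2 and 4245 without MDX_JJ101 replicate 2, and of 50 named genes that passed, 2, 4 and 33 still did in these cases, 43 without MDX_JJ101 replicate 1 and 46 without either MDX_tap array. With spike-in scaling 105 of 4393 genes were higher (median of all genes -0.46), and with median centring 8457 of 10102 were (0.39). For 1316 of the 7008 genes called in the main fit, 1 group was well above background on no array. Of 1543 called genes with several probes, 230 had a probe of opposite direction. Dmd was 6.42-fold lower (-2.68, SE 0.21, adjusted p = 0.00646; 0.000631 over the list alone), and it passed under each alternative, with adjusted p up to 0.0453. Utrn stood at -0.34 (SE 0.16, adjusted p = 0.147), and at 0.06 with median centring.

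The highest genes in MDX_JJ101 against B10_tap were Mthfd2, a mitochondrial folate enzyme gene, at 3.08 (SE 0.32, 8.48-fold, adjusted p = 0.00944), the kinase gene Mark1 at 2.99 (SE 0.43, 0.0128), Angptl4, an inhibitor of lipoprotein lipase, at 2.71 (SE 0.43, 0.0147) and Sprr1a at 2.61 (SE 0.37, 0.0123). Next were Chac1 at 2.60, the stress cytokine gene Gdf15 at 2.58, Ndrg4 at 2.57 and the metallothionein gene Mt2 at 2.56. Lowest among genes with a measured level in both groups were Tnnc2 at -4.35 (SE 0.82, 20.3-fold, 0.0196), Rnu3b1 at -3.90 (SE 0.66), Rnu1b6 at -3.54 (SE 0.41), Rnu2-10 at -3.33 (SE 0.47), Dmd, Pvalb at -2.68 (SE 0.65), the fast troponin I gene Tnni2 at -2.57 (SE 0.74, 0.0499) and Rmrp at -2.52 (SE 0.36). Both MDX_JJ101 arrays lay beyond both B10_tap arrays on each of them, as the naming rule required.

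By camera, 9 lists passed in MDX_JJ101 against B10_tap, 7 upwards and 2 downwards, and 0 with an estimated correlation, where each of the 9 had adjusted p = 0.885 with an estimated correlation. There 1 list had an unadjusted p under 0.05 (0.0345), and fry passed 1 list, heat shock and ER stress (adjusted p = 0.0205). Without MDX_JJ101 replicate 2 camera passed 5 lists. Glycolysis and glycogen genes rose in 10 of 18 members (12 over the list alone; median 0.52, adjusted p = 0.000363), with Tpi1 at 0.73, Gpi1 at 0.81, Pgam2 at 0.56 and Gys1 at 0.78. Atrophy and autophagy genes rose in 9 of 17 members (10 over the list alone; median 0.60, adjusted p = 0.00345), with Map1lc3b at 0.83, Gabarapl1 at 0.83, Eif4ebp1 at 0.65 and the autophagy receptor gene Sqstm1 at 1.34. Oxidative phosphorylation genes rose in 8 of 29 members (8 over the list alone; median 0.24, adjusted p = 0.0036), whereas their median was -0.22 under spike-in scaling. Cyc1 rose by 0.55, Uqcrc1 by 0.73, the citrate synthase gene Cs by 0.67 and Mdh2 by 0.49. Heat shock and ER stress genes rose in 8 of 15 members (8 over the list alone; median 0.41, adjusted p = 0.00423), whereas their median was -0.04 under spike-in scaling. The small heat shock protein genes Hspb1, Cryab and Hspb7 rose by 1.00, 0.79 and 0.85, and Hsph1 rose by 0.76. Antioxidant genes rose in 7 of 25 members (6 over the list alone; median 0.27, adjusted p = 0.00716) and had a median of -0.19 under spike-in scaling. Mt2 rose by 2.56, Mt1 by 1.24, Gsr by 0.55 and Gss by 0.55. Fatty acid oxidation genes rose in 7 of 22 members (7 over the list alone; median 0.40, 0.00813) and had a median of -0.06 under spike-in scaling. Ppard rose by 0.82, Ppara by 0.61, Mlycd by 0.70 and Acads by 0.92. Under spike-in scaling the glycolysis and atrophy medians were 0.059 and 0.14, with both calls kept. Median centring raised the 6 medians of this paragraph to between 0.64 and 1.0. The antioxidant call ended with normexp and quantile normalization (median 0.11, 0.123), quantile normalization alone (0.096, 0.119) and the authors' table (0.13, 0.109), and the fatty acid call with quantile normalization alone (0.26, 0.059). Under these scalings the heat shock median was 0.22 to 0.25, and the authors' table put the oxidative phosphorylation and fatty acid medians at 0.13 and 0.25, the latter being 0.26 with normexp and quantile normalization.

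Muscle stress genes rose in 8 of 12 members (8 higher and 1 lower over the list alone) in MDX_JJ101 against B10_tap, with a median of 0.75 (adjusted p = 0.00813, and adjusted p = 0.885 with an estimated correlation as for each list here). Gadd45b rose by 1.17 (SE 0.15), Flnc, which encodes filamin C, by 1.20 (SE 0.16), Ankrd1 by 1.09 (SE 0.16) and Nmrk2 by 1.78 (SE 0.28). Endothelial genes fell in 6 of 11 members (6 over the list alone; median -0.54, adjusted p = 0.0282), with Tek at -0.89, Kdr at -0.93, Cdh5 at -0.65 and Emcn at -0.54. Red blood cell genes fell in 3 of 7 members (3 over the list alone; median -0.91, adjusted p = 0.0348), the globin genes Hbb-b2 at -1.40, Hbb-b1 at -1.38 and Hbb-bt at -1.24, and Slc4a1 stood at -0.91 without passing. Without B10_tap replicate 1 these globin values were -0.89, -0.89 and -0.78, and the median of the list was -0.54. The calls that ended without 1 array were, without MDX_JJ101 replicate 2, those of the antioxidant (0.0653), fatty acid (median 0.20, 0.105), oxidative phosphorylation (median 0.15, 0.0519), endothelial (0.0519) and red blood cell (0.073) lists. Without MDX_JJ101 replicate 1 and without B10_tap replicate 1, the endothelial (0.0549 and 0.0887) and red blood cell (0.115 and 0.0765) calls ended. Under spike-in scaling the muscle stress, endothelial and red blood cell medians were 0.29, -1.0 and -1.37, and with median centring they were 1.15, -0.14 and -0.51. The endothelial call ended in both cases (0.315 and 0.0964), and the red blood cell call ended with array weights (0.0937). Without a filter the antioxidant, oxidative phosphorylation, fatty acid, atrophy, heat shock and muscle stress calls ended (adjusted p from 0.0953 to 0.208).

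The other 22 lists did not pass in MDX_JJ101 against B10_tap. Fast fibre genes fell in 7 of 12 members and rose in 2 (7 and 2 over the list alone; median -2.63, or -2.01 with bounds, adjusted p = 0.262), with Myh4 at least 54.4-fold lower. Dystrophin complex genes rose in 6 and fell in 2 of 15 (median 0.06), regeneration genes fell in 3 of 11 (0.02) and genes of the list of slow and oxidative fibres rose in 3 and fell in 1 of 11 (0.16). Medians were 0.32 for fibrosis (3 rose and 2 fell of 27, adjusted p = 0.0542), 0.07 for macrophages (1 of 22 rose), -0.38 for T and NK cells (2 of 13 fell), -1.19 for B and plasma cells (4 of 6 fell), -0.60 for neutrophils (3 of 5 fell), 0.66 for mast cells (2 rose and 1 fell of 7) and -0.22 for cytokines (3 of 22 rose). Interferon genes had -0.30 (3 of 17 fell, 0.0516), NADPH oxidase 0.19, calcium handling 0.31 (6 rose and 2 fell of 19), adipocytes -0.57 (2 rose and 5 fell of 11), smooth muscle -0.26 (2 rose and 2 fell of 10), Schwann and nerve -0.52 (3 of 9 fell), cell cycle 0.003, circadian clock 0.04, immediate early 0.06 (1 of 15 rose), ribosomal protein -0.06 (2 of 22 fell) and the sex check -0.16. The Y-linked Ddx3y, Eif2s3y and Uty stood at -0.41, -0.16 and 0.13. Over the list alone the counts differed for the dystrophin complex (7 rose), fibrosis (1 rose), macrophages, T and NK cells, interferon, immediate early and ribosomal genes (0 each), mast cells (2 fell), cytokines (2 rose), calcium handling (7 rose, 3 fell), adipocytes (3 rose), smooth muscle (5 fell) and nerve (1 rose). Mean or test differed in sign from the median for the dystrophin complex (mean -0.01), regeneration (mean -0.34, test downwards), cytokines (test upwards), slow fibre (mean -0.07), cell cycle (mean -0.02) and circadian clock (mean -0.03).

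Whether genes that differed in MDX_tap moved back with JJ101 was asked across the 20869 genes, which are not independent replicates. The correlation of the MDX_tap against B10_tap differences with the MDX_JJ101 against MDX_tap differences was -0.26 (Spearman -0.24). Because both share the MDX_tap arrays, simulated data without effects gave -0.50 (-0.54 to -0.46). The covariance was -0.080 against a simulated -0.026, and 60.7% of genes had opposite signs against 66.7% in the simulation. List medians of opposite sign in the first and second comparisons, such as those of macrophage genes, can come from the shared arrays in the same way. The correlation was -0.43 without MDX_tap replicate 1 or 2 and -0.12 without MDX_JJ101 replicate 2. The simulated -0.50 applies to the fit of all arrays, and no such value is given for these fits, so they cannot be set against it. The differences of MDX_tap and MDX_JJ101 from their shared B10_tap arrays correlated at 0.42 (Spearman 0.29) against a simulated 0.50 (0.46 to 0.55), with a covariance of 0.136 against 0.026.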

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

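The tests of explanations in this part were chosen after the results they bear on were seen. The difference between the MDX groups was singled out because the shift of a gene from B10_tap was tested for being unlike between MDX_JJ101 and MDX_tap, and 7529 genes passed.

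The first pattern is that breadth, with 7529 genes past the threshold between the MDX groups, among them Zbtb16 and Rnu3b1, and 5 between the tap water groups. At an unadjusted p under 0.05 by limma the counts were 10364 and 4383. With the slide column as a block 0 genes passed between the MDX groups. The replicate block, which groups the MDX arrays in the same way, left 6517 genes. A block also lowers the residual degrees of freedom, so the 0 does not show that slide column gave the breadth. The counts of 7529 and 5 also moved with single arrays, as given above, so the contrast depends on the threshold and on the arrays fitted. The tables argue against scaling as the cause of the breadth. Under each other scaling but that on spike-ins, 6164 genes or more passed. The lowest ratio to the count between the tap water groups under the same scaling was 18.3. Spike-in scaling gave 3712 genes, 8.99 times the count between the tap water groups, but its adjusted p values are not on a footing with the rest. Scaling stays open for the direction of the calls, since spike-in scaling left 79 genes called higher in place of 4160, while the spike-in factor differed by 0.46 between the MDX_tap arrays and by 0.51 between the MDX_JJ101 arrays, as much as the 0.43 between the groups. Position on the slide stays open, because JJ101 and slide row cannot be told apart, and the MDX_JJ101 arrays had the widest spatial trends (2.75 and 4.11 against 0.998 to 1.51 on the others) and negative control spreads (3.17 and 3.33 against 2.14 to 2.78). The SD of the spike-in differences between the MDX groups was 0.0381 against 0.663 for genes, but the 7 spike-ins used were all bright and say nothing about dim spots. An effect of JJ101 itself was not tested apart from scaling and position. Other causes of the breadth, among them the differing tissue content considered below, were not tested either. All 8 small non-coding RNAs measured fell as well (median -3.41), a fall whose cause is equally untested.

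The second pattern is heart-type transcripts in samples labelled gastrocnemius. The tables argue against binding of skeletal muscle relatives to the probes of heart contractile genes, since 100% of the 12 heart regulators and hormones, which are no relatives of bright skeletal genes, were well above background on all arrays. They also argue against heart genes being switched on by dystrophy, since the heart contractile list had a median of -0.17 in MDX_tap against B10_tap and Myh6 had a level of 10.42 in wild-type mice. The heart regulators and hormones had a median of 0.01 there with 6 of 12 positive. Single genes such as Nppa were higher in MDX_tap, the highest value of that list being 1.46. That heart RNA made up most or all of the RNA is a hypothesis with which the values are consistent: 12 of 12 heart regulators and hormones, and 4 of 20 limb muscle regulators, were well above background on all arrays. How the tissue was taken is not known here, so a mixture with skeletal muscle stays open.

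The third pattern is the fall of fast fibre transcripts such as Myh4 and Tnnc2 in MDX_JJ101 against MDX_tap. The scaling of the arrays is argued against, since the median of the 6 fast fibre genes that fell was -2.10 or lower under each of 5 other scalings. Skeletal muscle RNA present in differing amounts would go with a median difference of 2.60 in the same genes between the MDX_tap arrays (2.02 to 2.97, replicate 2 higher), where the SD over all genes was 0.37. However, 2 members of the fast fibre list, Atp2a1 and Mybpc2, rose between the MDX groups, so this explanation stays open. A shift from fast to slow fibres stays open, because skeletal muscle genes of any fibre type had a median of -0.36 (-0.79 to -0.066 under other scalings or without 1 array) with members on both sides of 0. Stac3 and Ryr1 fell among them and Lmod3 rose. The rise of Atp2a1 and Mybpc2 also goes against a shift of all fast fibre genes. The difference of 2.60 lay between the MDX_tap arrays, which shared their water, so a shift through JJ101 would not account for it.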

How the results depend on the processing

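Scaling on spike-ins, list tests with every probe and the alternatives for lists chosen later were added after the data were seen; the other alternatives were planned. Signal over background limits which dim transcripts were measured. Where a value moved, the cause was not tested. Leaving out an array or a group, or adding a block, does lower the residual degrees of freedom. In the fits without 1 array, the lone array is assumed to vary like the other groups. The alternative without saturated spots was not run, since no spot was saturated, and the slide column block was fitted only for MDX_JJ101 against MDX_tap.

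For MDX_tap against B10_tap, the count of 5 genes became 407 with normexp, quantile normalization and the median signal together (302 higher, 105 lower), 285 with median centring (242 and 43), 348 with the authors' table (266 and 82), 0 without a filter by limma (5113 at an unadjusted p under 0.05), 151 with the filter on all arrays, 351 with a floor, 15 with every probe, 391 with trend and robust variances, 378 with array weights, 413 with spike-in scaling (204 and 209), 125 with 2 groups fitted and 17 to 190 without 1 array. Quantile normalization gave 4 (1 higher, 3 lower). For MDX_JJ101 against MDX_tap, the count of 7529 (4160 higher, 3369 lower) became 1718 at 2-fold or more, 13640 without a filter, 3712 with spike-in scaling (79 and 3633), 4816 with 2 groups fitted, 0 with the slide column block by limma (8857 at an unadjusted p under 0.05) and 0 to 7978 without 1 array. Median centring gave 7590 (5692 and 1898). For MDX_JJ101 against B10_tap, the count of 7008 (3376 and 3632) became 1971 at 2-fold or more, 14092 without a filter, 4393 with spike-in scaling (105 and 4288) and 427 to 7205 without 1 array, and median centring gave 10102 (8457 and 1645).

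Of the gene lists, 13, 14 and 9 passed in the comparisons in the order above, against 0, 0 and 0 with an estimated correlation and 1, 1 and 1 with fry. In the last comparison 4 passed without a filter. Without 1 array, 10 to 17, 8 to 18 and 5 to 12 lists passed. With every probe 14, 17 and 11 did. Of the called lists, 7 of 13, 6 of 14 and 1 of 9 kept their call in all alternatives that changed neither the correlation nor the list test. The correlation of the MDX_tap against B10_tap differences with those of MDX_JJ101 against MDX_tap was -0.39 with normexp and quantile normalization and -0.43 to -0.12 without 1 array. Their correlation with those of MDX_JJ101 against B10_tap was 0.29 with normexp and quantile normalization, 0.29 with the filter on all arrays and 0.31 to 0.56 without 1 array. For these alternatives no simulated value without effects is given. Direction turned for the interferon list in MDX_tap against B10_tap, which ranged from -0.037 to 0.56 without 1 array, and for Utrn, which ranged from -0.10 to 0.27 there and was 0.063 with median centring in MDX_JJ101 against B10_tap. List medians also turned for ribosomal proteins with median centring (MDX_JJ101 against MDX_tap), and under spike-in scaling for antioxidants and oxidative phosphorylation in both MDX_JJ101 comparisons and for fatty acid oxidation and heat shock in MDX_JJ101 against B10_tap. No named gene past the threshold turned direction in any alternative, but many calls ended. Of 72 named calls in MDX_JJ101 against MDX_tap, 43 were kept with spike-in scaling and 0 with the slide column block. Of 50 in MDX_JJ101 against B10_tap, 23 were kept with spike-in scaling. Values also shrank: the lowest over all alternatives was 0.32 for Cyc1 and 0.20 for Sod2 in MDX_JJ101 against MDX_tap. For Mdh2 in MDX_JJ101 against B10_tap it was 0.033.

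The labels of the groups share only replicate numbers, while MDX_tap and MDX_JJ101 arrays of the same number also share a slide column. With a replicate block 4, 6517 and 5863 genes passed in place of 5, 7529 and 7008, and the replicate differences correlated at -0.03 between B10_tap and MDX_tap, -0.06 between B10_tap and MDX_JJ101 and 0.16 between MDX_tap and MDX_JJ101.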

Other observations

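The gene lists and the test in this part were chosen after the values were seen, and the lists were then run under 5 other scalings and without each array, at the preset correlation. Some lists hold genes already named above as the most changed, such as Zbtb16, Mt2 and Mthfd2. Their tallies and p values therefore describe the patterns that prompted the lists and are no independent test of them. Genes of the amino acid response, which raise amino acid synthesis and uptake when supply is short, rose in 13 of 15 members in MDX_JJ101 against B10_tap and fell in 1, Pck2 (median 1.07, camera adjusted p = 9.1e-05, and adjusted p = 0.313 with an estimated correlation). Besides Mthfd2 and Chac1, the asparagine synthetase gene Asns rose by 1.54 and the serine synthesis genes Psat1 and Phgdh by 1.07 and 1.13. In MDX_JJ101 against MDX_tap 6 rose and 1 fell (median 0.63, 0.00723, and 0.408 with an estimated correlation), and in MDX_tap against B10_tap the median was 0.29 with 0 genes past the threshold (0.00215, and 0.377 with an estimated correlation). These calls were kept in those runs, but spike-in scaling put the first 2 medians at 0.61 and 0.20, and the second was 0.39 with normexp and quantile normalization and 0.42 without MDX_JJ101 replicate 1. The third was 0.47 with median centring and 0.12 without MDX_tap replicate 1. Genes induced by glucocorticoids rose in 12 of 16 members in MDX_JJ101 against B10_tap, with all 16 positive (median 1.61, 1.7e-06, and 0.313 with an estimated correlation). Fkbp5, which encodes a chaperone partner of the glucocorticoid receptor, rose by 2.02, the cell cycle inhibitor gene Cdkn1a by 2.29 and Ddit4 by 1.98. In MDX_JJ101 against MDX_tap 8 rose and 1 fell, Sgk1 (median 0.58, 0.0168, and 0.586 with an estimated correlation), and in MDX_tap against B10_tap the median was 0.55 with 0 past the threshold (2.8e-05, and 0.377 with an estimated correlation). The first of these medians was 1.07 with normexp and quantile normalization. The call between the MDX groups ended with quantile normalization (median 0.39, 0.0513) and without MDX_JJ101 replicate 2 (0.37, 0.0825). Its median was 0.15 with spike-in scaling, 0.39 with normexp and quantile normalization, 0.91 without MDX_tap replicate 2 and 1.16 without MDX_JJ101 replicate 1.

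Of 10 genes of a liver list that met the filter, 9 met it through the B10_tap arrays alone, so that no list test is given. The albumin gene Alb was at least 7.95-fold lower in MDX_tap than in B10_tap without passing (adjusted p = 0.130), and in MDX_JJ101 against B10_tap Cps1 fell at least 3.12-fold (0.0081) and Mup1 fell (0.0494). Serpina1a, well above background on all arrays, stood at -1.82 and -1.88 in these comparisons without passing (0.271 and 0.124). Beside the small non-coding RNAs named in the report, Rnu12 fell by 1.13 in MDX_JJ101 against MDX_tap. Snora47 and the telomerase RNA Terc, well above background on neither MDX_JJ101 array, were at least 6.05-fold and 1.35-fold lower. Snora74a, well above background on 1 of those arrays, fell as well. All 8 small non-coding RNAs measured thus fell in that comparison (median -3.41). In MDX_tap against B10_tap 7 of them were positive and 0 passed. The cause of this fall was not tested.

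Heart contractile genes had medians of 0.47 in MDX_JJ101 against MDX_tap (3 of 8 rose, camera adjusted p = 0.0168, and 0.586 with an estimated correlation) and 0.24 in MDX_JJ101 against B10_tap (1 rose, 0.15). Spike-in scaling put them at 0.043 and -0.22. The call between the MDX groups ended with that scaling (0.0897), with quantile normalization (0.0886) and without MDX_tap replicate 1 (median 0.31, 0.0563) or MDX_JJ101 replicate 2 (0.0567). The other median was 0.64 with median centring, 0.15 with quantile normalization or the authors' table and 0.14 without MDX_JJ101 replicate 2. Heart regulators and hormones had medians of 0.56 (5 of 12 rose, 0.00723, and 0.408 with an estimated correlation), 0.55 (6 rose, 0.000458, and 0.313 with an estimated correlation) and, in MDX_tap against B10_tap, 0.01 (0.646), where the medians ran from -0.13 without MDX_tap replicate 2 to 0.18 with median centring. Both calls of this list were kept in those runs, with medians down to 0.13 and 0.093 under spike-in scaling, while the second rose to 0.95 with median centring. Limb muscle regulators had medians of -0.17, 0.08 and 0.05 in the comparisons in the report's order, none of fixed direction under the other scalings, and of the 8 measured Hoxd8 fell in MDX_JJ101 against MDX_tap.

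Clock output genes were negative in all 8 members in MDX_tap against B10_tap (median -0.88, camera adjusted p = 2.5e-06, and 0.347 with an estimated correlation), and 6 rose in MDX_JJ101 against MDX_tap (median 0.73, or 0.30 with spike-in scaling, 0.00723, and 0.408 with an estimated correlation). All 8 were taken from the fixed clock list after its values were seen, so these values describe the pattern and do not test it. Tissue collected at a different time of day was taken as a hypothesis, which predicts that the activators of the clock move against the genes of the clock output list. The mean of the activators was 0.86 in MDX_tap against B10_tap and -0.35 in MDX_JJ101 against MDX_tap (-0.78 with spike-in scaling, -0.13 with median centring, -0.22 without MDX_tap replicate 2), but only 2 were measured and neither passed in either comparison. Arntl stood at 1.17 and -0.20 (adjusted p = 0.141 and 0.597) and Clock at 0.55 and -0.50 (0.159 and 0.0536). Time of day therefore stays open, as does an effect of genotype on the clock, which was not tested.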
